A study of Arabidopsis thaliana with 72 samples.

How the data were processed

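Total RNA from aerial tissue of seedlings was labelled with biotin by the one-cycle protocol and hybridised to ATH1 arrays, 72 in all. The deposited values are intensity on a linear scale, made by the authors with MAS5 and GCOS per the submitters' processing notes, whose versions are not stated. The mean of each deposited array, without the highest and the lowest 2% of probe sets, was 100 signal units, which was checked on the values. Arrays have no read depth, and their number sets the precision.

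Signals were taken as log2(signal + 16), which understates fold changes of transcripts near the lower limit. Of 22810 probe sets, 64 controls were set aside and the upper 60% by mean log2 value over all arrays were tested, 13647 in number. A linear model with a mean for each of the 36 combinations of condition and time was fitted in limma 3.58.1 with R 4.3.3 (files read with data.table, version 1.17.8), with moderated variances and an intensity trend (36 residual and 6.74 prior degrees of freedom). Adjusted p values are Benjamini-Hochberg values and the threshold was 0.05. Rhythm was tested with moderated F tests of the 24 h cosine and sine terms, and a difference of rhythm with the differences of those terms. Amplitude differences used a delta-method standard error from limma's moderated variance, over probe sets rhythmic in either condition. Mean levels were contrasted over the 12 times, and each time was also contrasted by itself. Standard errors come from this fit, in which all conditions share a single estimate of the spread for each probe set. Replicates are not stated to be independent seedling batches, so p values measure only the spread between these samples.

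One period per time course was found on a grid from 18 to 34 h in steps of 0.1 h. It used a single cosine for each of the fixed clock genes with a named probe set, 3 of 28. Peak shifts were taken over 636 probe sets rhythmic in all conditions. Gene lists were tested with camera at a correlation of 0.01, with camera at an estimated correlation, and with fry, with 1 probe set per gene, the one of highest mean. fry tests whether the genes of a list move on balance 1 way and compares them with no other genes.

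Probe sets took a gene name only from the supplied annotation of the array, where 13513 had 1 gene, 503 several and 8794 none listed. The identifiers of 13436 were matched to a reference annotation for current names, and 7282 tested probe sets had a gene. Of the 269 genes in 15 lists, 36 were named there and 29 tested, so lists rest on few members. That annotation names no probe set for the gene mutated in toc1-1, and it is not reported here. Positions are not used here. Of the genes with several probe sets, 62 in number, 1 was called both ways under nicotinamide and 3 in toc1-1. The named gene among them, AT2G37480, has probe sets that moved the same way.

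Named genes followed a rule. For mean levels these are the 10 highest and 10 lowest with an adjusted p under 0.05, 1 gene and the same direction in both time courses. For amplitudes they are the 10 of largest untreated amplitude per direction, for the calcium pattern the 10 of largest untreated amplitude, and for each list up to 4 members with the smallest adjusted p. The comparisons, tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. The 15 families defined by gene symbol were written after that annotation was seen and before values were examined, the minimum of 2 members for a list test was set later, and 31 root hair genes were listed after the fall of root-type peroxidases was seen. COR15A and the converse pattern's members are named outside that rule.

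The procedure was tested on simulated data with independent noise. A mean change of 0.5 was recovered in 97% of probe sets and one of 1 in 100%. An amplitude of 0.3 was called rhythmic in 59% and one of 0.6 in 100%. The loss of an amplitude of 0.3 was called in 55% and of 0.6 in 98%, and the calcium pattern in 35% and 96%. There the amplitude was set to 0 under nicotinamide and left at the untreated size in toc1-1. Partial losses, or a lower amplitude in toc1-1 as well, are harder to call and were not simulated. False calls were 6 and 1 for mean levels in nicotinamide and toc1-1, 7 for rhythm in untreated seedlings and 0 for the calcium pattern. All 3 raised lists were called, with 1 other list. Simulated periods of 21, 24 and 27 h were returned as 21.0 ± 0.288 h, 24.0 ± 0.389 h and 27.0 ± 0.495 h (SD, n = 100 series).

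Alternatives were quantile normalization, pseudocounts of 1 and 64, no filter and a filter to the upper 40%, an adjusted p under 0.01, a minimum change of 1.5-fold, a replicate term, time courses as a random block, time course means, no intensity trend, no probe sets shared between transcripts, no arrays with a title ending in 2 (3 arrays), a linear trend, the period of each condition, the spread of the cosine residuals, and each replicate time course left out. Leaving out times or arrays that stood apart was added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.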

Results

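Transcript levels were measured in aerial tissue of Arabidopsis seedlings on 72 ATH1 arrays. Seedlings grew in cycles of 12 h light and 12 h dark for 11 days and were then moved to continuous light. The arrays covered 3 conditions: untreated C24 wild type, C24 wild type treated with nicotinamide, and the mutant toc1-1. Each condition had 24 arrays, which were 2 replicate time courses of 12 times, every 4 h from 49 to 93 h. Nicotinamide is an inhibitor of ADP-ribosyl cyclase known to abolish the daily oscillation of cytosolic free calcium, and toc1-1 is a clock mutant of short period. The series title asks for circadian transcripts regulated together with cytosolic free calcium.

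The median signal of an array, after scaling by the authors, was 35.2 ± 1.49 in untreated seedlings (SD, n = 24), 26.5 ± 3.38 under nicotinamide (SD, n = 24) and 35.5 ± 0.990 in toc1-1 (SD, n = 24). The number of arrays limits the precision. The correlation of log2 signals between the replicates of a time had a median of 0.979 across probe sets, and its lowest value was 0.919. The first principal component held 54.5% of the variance and separated nicotinamide from the other arrays. The nicotinamide arrays of 77 h (replicate 1) and 85 h (replicate 2) stood apart from the other nicotinamide arrays. Of the control transcripts, the log2 ratio of the 3-prime to the 5-prime probe sets of actin was 1.13 ± 0.16 in untreated seedlings, 1.19 ± 0.26 under nicotinamide and 1.37 ± 0.28 in toc1-1 (SD, n = 24 each). In the same order it was 0.66 ± 0.12, 0.47 ± 0.14 and 0.78 ± 0.22 for ubiquitin and 0.40 ± 0.16, 0.39 ± 0.18 and 0.52 ± 0.22 for GAPDH (SD, n = 24 each). The 25S ribosomal RNA control had log2 levels of 7.70 ± 1.01 in untreated seedlings, 7.89 ± 0.80 under nicotinamide and 8.53 ± 0.93 in toc1-1 (SD, n = 24 each).

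Which transcripts cycled in continuous light was asked first in untreated seedlings. GI, a component of the circadian clock, had a 24 h amplitude of 1.36 ± 0.08 on the log2 scale (SE, n = 24 arrays) and peaked at 10.6 h, with hours counted modulo 24 from the times in the labels. COR27 and COR28, cold-regulated outputs of the clock, peaked at 13.7 h and 14.1 h with amplitudes of 1.81 ± 0.12 and 1.1 ± 0.09. LHCB4.2 and LHCB4.3, light-harvesting proteins of photosystem II, had amplitudes of 0.99 and 0.83. LHCB4.1 of the same list was not called rhythmic (0.11; adjusted p = 0.556, moderated F test). Of 13647 probe sets tested, 3129 (22.9%) were rhythmic in untreated seedlings, with a median amplitude of 0.32. Their peaks were spread over the day, with 713 from 0 to 6 h, 893 from 6 to 12 h, 694 from 12 to 18 h and 829 from 18 to 24 h. By the same test 4371 (32.0%) were rhythmic under nicotinamide and 1166 (8.54%) in toc1-1, and 636 were rhythmic in all 3 conditions. The nicotinamide count is not separated from chance, since 15 of 100 orders of the times, the real one included, gave as many calls. Its place above untreated also moved, to 2367 against 3113 without the 3 arrays of title ending 2 and to 3921 against 4603 without nicotinamide replicate 2. Those 3 arrays are nicotinamide 49 h replicate 1 and both replicates of 65 h, so nicotinamide lost a whole time there. With a replicate time course left out the untreated count ranged from 1305 to 4608 and that of toc1-1 from 211 to 2091. Conditions share a single estimate of the spread, so the untreated count also rose without nicotinamide replicate 2, with every untreated array kept. The lowest replicate correlation was 0.919 under nicotinamide, against 0.970 in untreated seedlings and 0.962 in toc1-1. The counts of the conditions are thus not each judged by their own spread.

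**Figure D1:**
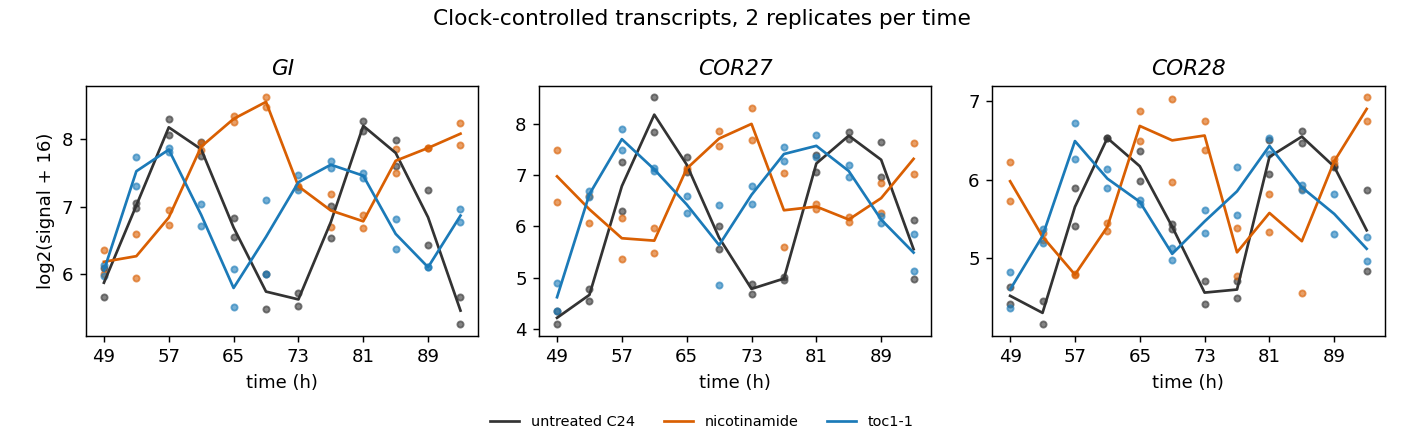
Levels of GI, COR27 and COR28 as log2(signal + 16) against time in h. Points are single arrays and lines join the means of the 2 replicates of each condition. GI peaked at 10.6 h in untreated seedlings, 17.55 h under nicotinamide and 6.5 h in toc1-1 (fitted 24 h cosine, modulo 24).

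Nicotinamide was compared with untreated wild type to find which transcript rhythms differ; calcium itself was not measured on these arrays. GI peaked at 17.55 h in place of 10.6 h, and its amplitude was 0.93 against 1.36 (± 0.08 each, SE, n = 24; adjusted p = 0.00687, limma). COR27 peaked at 22.3 h in place of 13.7 h, and its amplitude was 0.88 against 1.81 (± 0.12 each; adjusted p = 9.02e-05). No change of amplitude was called for COR28 (0.88 against 1.1; adjusted p = 0.207) or for the clock output CDF5 (0.68 against 0.52; adjusted p = 0.326), which peaked at 20.6 h and 14.7 h in place of 14.1 h and 5.17 h. CCL, a transcript of the CCR-like family, had an amplitude of 0.93 under nicotinamide and 1.55 in untreated seedlings (adjusted p = 0.000547). The lowest amplitude among the 10 named transcripts was that of AT5G62360, at 0.55 against 1.96 (adjusted p = 1.99e-07). The others were AT4G32340 (0.87 against 1.67), AT2G27420 (0.93 against 1.62), AT2G15020 (0.62 against 1.61), AT4G16146 (0.66 against 1.5), AT1G07050 (0.79 against 1.48) and AT5G42760 (0.92 against 1.32).

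Other transcripts cycled with greater amplitude under nicotinamide. They included 2 enzymes of leucine breakdown, MCCA with 0.72 against 0.39 (± 0.06 each, SE, n = 24; adjusted p = 0.0127) and IVD with 0.71 against 0.26 (± 0.08 each; adjusted p = 0.00813). The triacylglycerol lipase SDP1 had 0.56 against 0.27 (adjusted p = 0.0239), and the glutamine amidotransferase GAT1_2.1 had 1.09 against 0.47 (adjusted p = 0.0312). The other named transcripts were AT2G43550 (0.83 against 0.41), AT3G52740 (0.61 against 0.32), AT1G02660 (0.77 against 0.30), AT1G07280 (0.61 against 0.26), AT4G27280 (0.71 against 0.21) and AT1G51790 (0.50 against 0.20). In untreated seedlings GAT1_2.1 ranged only from 4.12 to 5.95 on the log2(signal + 16) scale, and AT1G02660 from 4.78 to 5.89. At such low levels the added 16 units compress the untreated amplitude. For both, a greater amplitude therefore cannot be told apart from a rise in level. With quantile normalization GAT1_2.1, AT3G52740, SDP1 and AT1G51790 were no longer called. Of the 46 named amplitude results of both comparisons, 16 lost their call with the spread of the cosine residuals and 9 with a linear trend. With the period of each condition in place of 24 h, 5 of them lost their call.

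The rhythm differed between nicotinamide and untreated seedlings in 3536 probe sets (moderated F test of limma), the amplitude was lower in 496 and it was higher in 163. At an unadjusted p under 0.05, 1001 were lower and 929 higher of 5993 tested. Without nicotinamide replicate 1 the order reversed, with 507 lower and 1308 higher, and without replicate 2 there were 519 and 722, so which direction prevailed is not settled. When a replicate time course was left out the count of 3536 ranged from 1646 to 5095 and that of 496 from 243 to 519. The count of 163 moved with single nicotinamide arrays: it was 570 without 53 h replicate 1, 261 without 57 h replicate 1, 478 without 77 h replicate 2 and 301 without 85 h replicate 2. It ranged from 16 to 1308 when a replicate time course was left out.

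The period shared by GI, COR27 and COR28 was 23.7 ± 0.424 h in untreated seedlings (SD, n = 2 time courses), 25.7 ± 0.707 h under nicotinamide (SD, n = 2) and 21.65 ± 0.0707 h in toc1-1 (SD, n = 2). GI alone gave 24.35 h, 26.8 h and 21.1 h. Over both time courses the period of GI differed from untreated in nicotinamide (adjusted p = 0.0498) and in toc1-1 (adjusted p = 0.000102; extra-sum-of-squares F tests over 24 and 24 arrays). That of COR27 differed under nicotinamide (adjusted p = 0.0498) but not in toc1-1 (adjusted p = 0.0728), and that of COR28 passed the threshold in neither (adjusted p = 0.0831 and 0.219). The 636 probe sets rhythmic in all conditions peaked 7.94 ± 0.0852 h later under nicotinamide than in pooled untreated arrays (SD, n = 2), and the delay was 7.24 ± 0.232 h in the first 24 h and 9.07 ± 0.473 h in the second. In toc1-1 the shift was -3.78 ± 0.312 h, with -2.77 ± 0.484 h in the first 24 h and -5.14 ± 0.127 h in the second (SD, n = 2 each). The exact permutation test of 2 against 2 time courses gave p = 0.333 for each shift, the smallest it can give, while the untreated time courses themselves stood at -0.49 and 0.51 h.

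**Figure D2:**
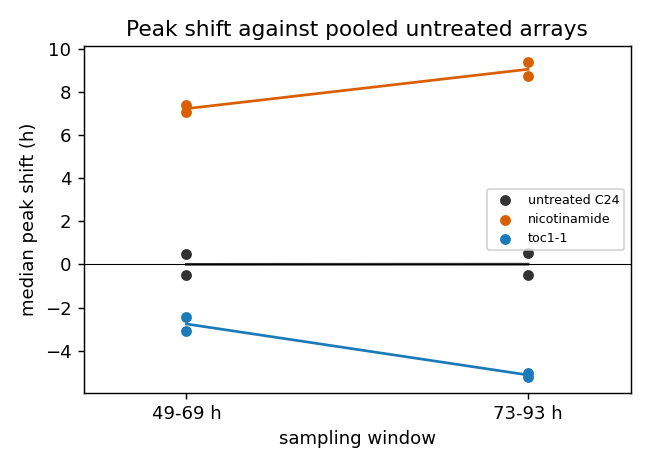
Median peak shift in h of the 636 probe sets rhythmic in all 3 conditions, against pooled untreated arrays, for the times 49 to 69 h and 73 to 93 h. Points are the 2 replicate time courses of each condition and lines join their means, which moved from 7.24 to 9.07 h under nicotinamide and from -2.77 to -5.14 h in toc1-1.

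Nicotinamide also changed mean levels over the whole time course. Ranked by log2(signal + 16) among named transcripts, the one raised most was AT5G64120, peroxidase 71, by 3.71 ± 0.11 on the log2 scale (SE, n = 24 and 24; adjusted p = 5.39e-30). ICL, the isocitrate lyase of the glyoxylate cycle, rose by 3.14 ± 0.08 (adjusted p = 4.23e-32) from a signal of 1.84 to 142, against 231 to 3219 for AT5G64120. On this scale the lowest was PDF1.2b, a plant defensin, at -4.15 ± 0.23 (adjusted p = 8.42e-21), with a signal of 559 in untreated seedlings and 16.3 under nicotinamide. By signal the order of the lowest would differ, but AT4G17470 (188 to 2.24), AT4G26010 (161 to 1.93), UGT75C1 (134 to 2.46) and AT4G01390 (158 to 4.25) fell to the lower limit, where a fold is only a bound. PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis, was at -2.94 ± 0.09 (adjusted p = 2.69e-30). Also among the 10 highest were AT4G12500 (3.58), AT3G46280 (3.31), AT2G04050 (3.23), AT5G39580 (3.12), AT5G48430 (3.07), AT4G12490 (3.07), AT3G04000 (2.73) and AT1G30700 (2.69). The 10 lowest further held AT4G17470 (-3.48), AT4G26010 (-3.30), AT1G29660 (-3.17), AT4G01390 (-3.10), the anthocyanin glucosyltransferase UGT75C1 (-3.02), AT3G45160 (-2.94), AT5G63180 (-2.85) and AT1G73600 (-2.81).

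In all, 4223 probe sets were higher and 6602 lower under nicotinamide (limma, 13647 tested), of which 656 and 1203 changed at least 2-fold. Of those called, 39.0% were higher, against 50.4% after quantile normalization, and the median log2 change of all probe sets moved from -0.12 to 0.005, so small changes are read relative to that shift. Calls at single times numbered 62622 in total, from 3077 at 49 h to 6891 at 85 h.

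**Figure D3:**
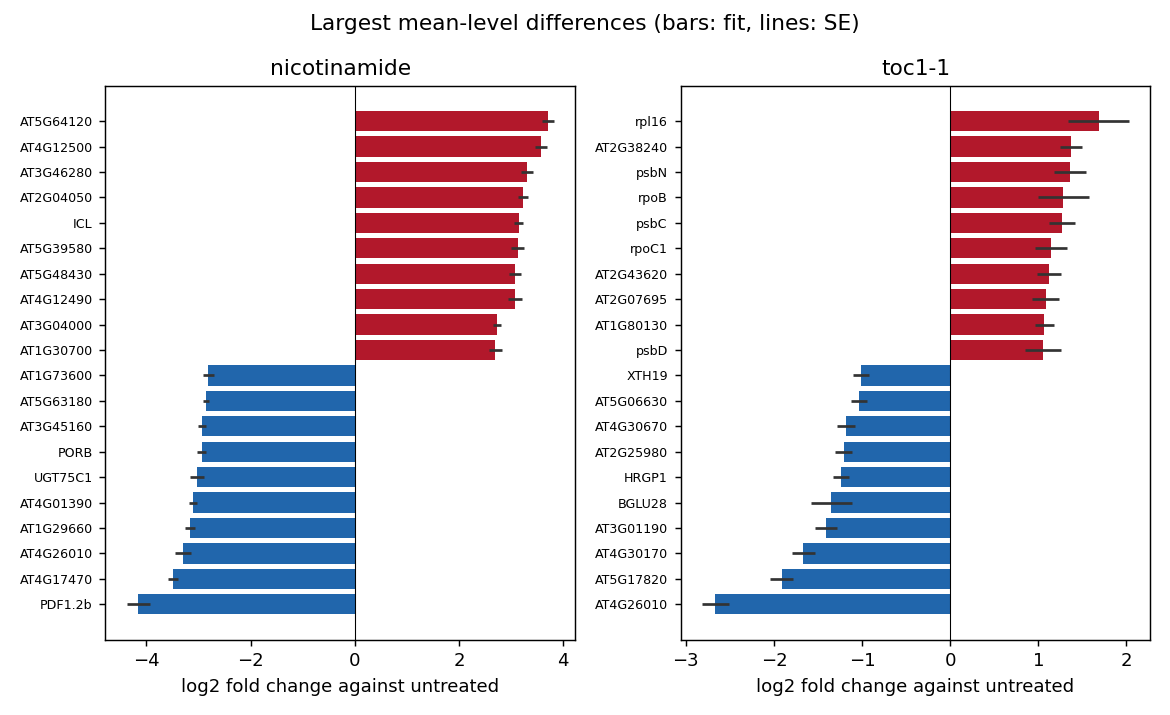
Log2 fold change of mean level against untreated for the 10 highest and 10 lowest named transcripts on the log2(signal + 16) scale under nicotinamide and in toc1-1. Bars are fitted values and lines are standard errors (n = 24 and 24 arrays). The bars reach from -4.15 to 3.71 under nicotinamide and from -2.67 to 1.68 in toc1-1, on axes of different range.

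The gene lists fixed in advance were tested under nicotinamide as groups and by member. The auxin list had 2 measured members, GH3.3 (2.33 ± 0.10) and GH3.5 (2.03 ± 0.08; SE, n = 24 and 24), which conjugate auxin to amino acids, and both rose. It was the one list called by camera at its preset correlation (adjusted p = 0.0253), with adjusted p = 0.062 with an estimated correlation, and 15 of 100 regroupings of the arrays called as many lists. After quantile normalization 4 lists were called, auxin and starch (adjusted p = 0.0441 each), light harvesting (adjusted p = 0.0468) and flavonoid (adjusted p = 0.0471). On the values as deposited, camera with an estimated correlation gave adjusted p = 0.291 for starch and 0.3 each for light harvesting and flavonoid. All 3 starch genes fell: APL3, a subunit of ADP-glucose pyrophosphorylase (-1.87 ± 0.13), DPE1, a disproportionating enzyme (-1.34 ± 0.07), and PWD, a phosphoglucan water dikinase (-1.24 ± 0.10; camera adjusted p = 0.0899). All 3 light-harvesting genes fell, with LHCB4.3 at -1.41 ± 0.09, LHCB4.2 at -0.86 ± 0.10 and LHCB4.1 at -0.28 ± 0.07 (camera adjusted p = 0.183). In the flavonoid list DFR (-2.79 ± 0.11), UGT75C1 (-3.02 ± 0.13) and UF3GT (-2.27 ± 0.12), which act late in anthocyanin synthesis, fell, while UGT78D2 rose by 0.35 ± 0.07 (camera adjusted p = 0.15).

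In the cold list the dehydrins COR47 (0.96 ± 0.12) and LTI30 (1.59 ± 0.17) and the zinc finger protein ZAT10 (1.76 ± 0.14) rose, and the chloroplast proteins COR15A (-0.62 ± 0.18) and COR15B (-0.87 ± 0.09) fell (camera adjusted p = 0.217). Of the calcium signalling genes, the chloroplast calcium sensor CAS fell (-2.06 ± 0.06) and the glutamate receptor GLR3.3 was at -0.21 ± 0.08, a call lost after quantile normalization at -0.005, while the calmodulin-like CML23 stood at 0.08 ± 0.12 without a call and was called higher after quantile normalization at 0.31 (camera adjusted p = 0.298). Of the core clock genes GI (0.56 ± 0.08) and RVE6 (0.30 ± 0.06) rose and TIC stood at 0.06 ± 0.06 (camera adjusted p = 0.188). The clock outputs COR27 (0.49 ± 0.12), COR28 (0.34 ± 0.09) and CDF5 (0.81 ± 0.09) all rose (camera adjusted p = 0.152). QPT, an enzyme of NAD synthesis, fell (-0.98 ± 0.14), and so did the root-expressed beta-glucosidase PYK10 (-0.70 ± 0.07). The oxidative stress gene GSTU25 stood at -0.04 ± 0.09 without a call, and was called higher after quantile normalization at 0.22. The counts adjusted over the list alone were the same for each of these lists under nicotinamide. With the means of the time courses as units GLR3.3, RVE6 and LHCB4.1 lost their call.

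The mutant toc1-1 was compared with untreated wild type. Its labels give no ecotype and more seeds plated than for C24, so background and density are not separated from the mutation. GI peaked earlier, at 6.5 h in place of 10.6 h, and its amplitude was 0.75 against 1.36 (± 0.08 each, SE, n = 24; adjusted p = 0.000536). COR27 peaked at 9.8 h with an amplitude of 1.08 against 1.81 (adjusted p = 0.00469). CCL had 0.65 against 1.55 (adjusted p = 1.68e-05), and TBL26, a trichome birefringence-like protein, had 0.36 against 1.24 (adjusted p = 0.00209). The other named transcripts of lower amplitude were AT5G62360 (1.09 against 1.96), AT3G62550 (1.04 against 1.76), AT2G27420 (0.82 against 1.62), AT2G15020 (1.11 against 1.61), AT4G16146 (0.95 against 1.5) and AT5G42760 (0.78 against 1.32).

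The rhythm differed between toc1-1 and untreated seedlings in 982 probe sets, and the amplitude was lower in 209 and higher in 0 (limma). The count of 982 ranged from 268 to 1842 when a replicate time course was left out. At an unadjusted p under 0.05, 906 were lower and 20 higher of 3254 tested. The count of 209 was 362 without untreated 93 h replicate 2, 138 without toc1-1 69 h replicate 2 and 132 without toc1-1 81 h replicate 2, and it ranged from 3 to 508 when a replicate time course was left out. With the period of each condition in place of 24 h it was 130.

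Mean levels differed less in toc1-1 than under nicotinamide in size. The 4 transcripts lowered most were class III peroxidases, AT4G26010 at -2.67 ± 0.15 (SE, n = 24 and 24; adjusted p = 1.23e-17), AT5G17820 at -1.91 ± 0.13, AT4G30170 at -1.67 ± 0.13 and AT3G01190 at -1.41 ± 0.12. They were also lower under nicotinamide, at -3.30, -2.30, -2.25 and -1.15. Genes of root hairs were also lower in both comparisons, 5 of 5 measured, such as AT1G30870 (-2.11 under nicotinamide and -1.81 in toc1-1). The root hair genes were listed after the fall of root-type peroxidases was seen, so they are no independent support. Below the peroxidases came the beta-glucosidase BGLU28 (-1.35), the hydroxyproline-rich glycoprotein HRGP1 (-1.24), AT2G25980 (-1.21), AT4G30670 (-1.18), AT5G06630 (-1.04) and the xyloglucan endotransglucosylase XTH19 (-1.01). Of the 10 highest, 6 were chloroplast-encoded: rpl16 (1.68 ± 0.35), psbN (1.36 ± 0.18), rpoB (1.28 ± 0.29), psbC (1.27 ± 0.15), rpoC1 (1.14 ± 0.18) and psbD (1.05 ± 0.20). The others were AT2G38240 (1.37 ± 0.13), AT2G43620 (1.12), AT2G07695 (1.08) and AT1G80130 (1.07). With the means of the time courses as units all 6 of these chloroplast-encoded genes lost their call, and so did AT2G43620, AT2G07695 and BGLU28.

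Of 67 chloroplast-encoded genes, 27 were higher in toc1-1, 5 lower and 35 not called, with a median of 0.25 (camera adjusted p = 0.00265; adjusted p = 0.549 with an estimated correlation). In the same arrays the actin controls were lower in toc1-1 at the 5-prime end (-0.49 ± 0.06, adjusted p = 2.65e-07) and in the middle (-0.40 ± 0.06, adjusted p = 1.21e-06). The 5-prime controls of GAPDH (-0.04 ± 0.06) and ubiquitin (-0.03 ± 0.06) were not called (adjusted p = 0.991 each), and the 25S ribosomal RNA control was at 0.83 ± 0.29 (adjusted p = 0.0876). Of 9 expansins, which loosen cell walls, 6 were lower in toc1-1 and 3 not called, among them EXLB1 (-0.89 ± 0.08), EXPA8 (-0.77 ± 0.11) and EXPB3 (-0.65 ± 0.06; camera adjusted p = 0.000727; adjusted p = 0.18 with an estimated correlation).

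No list fixed in advance was called by camera in toc1-1 (adjusted p of 0.562 or more), so the values that follow concern single members. COR47 (-0.76 ± 0.12) and LTI30 (-0.58 ± 0.17) were lower, and ZAT10 (0.56 ± 0.14) and COR15B (0.29 ± 0.09) higher. CAS (0.16 ± 0.06), GLR3.3 (0.24 ± 0.08), COR27 (0.33 ± 0.12) and APL3 (0.32 ± 0.13) were higher. GH3.5 (-0.28 ± 0.08), TIC (-0.20 ± 0.06) and LHCB4.3 (-0.25 ± 0.09) were lower, and none of the 4 flavonoid genes was called. Each of these calls except that of COR47 was lost with the means of the time courses as units and with the time course as a random block. Adjusted over the list alone, the core clock list had 2 lower in place of 1, the oxidative stress list 1 lower in place of 0 and the starch list 0 higher in place of 1.

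In all, 3017 probe sets were higher and 2674 lower in toc1-1 (limma), but 22 and 40 changed at least 2-fold. With the means of the time courses as units the counts were 103 higher and 198 lower, and with the time course as a random block 835 and 991. Calls at single times numbered 2019, from 18 at 93 h to 491 at 77 h. That total was 3130 after quantile normalization, 3321 without the 2 nicotinamide arrays that stood apart (chosen after the data were seen), 698 at an adjusted p under 0.01 and 258 to 9106 when a replicate time course was left out. The contrast of toc1-1 with untreated uses no nicotinamide array. The rise to 3321 therefore came through the spread shared by all conditions, and calls in toc1-1 depend on the nicotinamide arrays.

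The series title asks for transcripts that follow cytosolic calcium. Transcripts were therefore sought that cycled in untreated seedlings and in toc1-1 and had a lower 24 h amplitude under nicotinamide than in both. Enzymes of anthocyanin synthesis were among them. The amplitude of DFR, dihydroflavonol reductase, was 1.16 in untreated seedlings, 0.05 under nicotinamide and 0.79 in toc1-1 (± 0.11 each, SE, n = 24). UGT75C1 had 1.17, 0.04 and 0.77 (± 0.13 each), and UF3GT had 1.14, 0.04 and 0.75 (± 0.12 each). All 3 also fell in mean level under nicotinamide, where their mean signals were 18.3 for DFR, 2.46 for UGT75C1 and 6.16 for UF3GT, against 222, 134 and 91.2 in untreated seedlings. The nitrate transporter family gene AT3G21670 lost amplitude, 1.05 to 0.18 with 0.67 in toc1-1 (± 0.06 each), while its mean level rose by 1.24 ± 0.06 under nicotinamide.

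AFR, an F-box protein of far-red light responses, had amplitudes of 0.94 in untreated seedlings, 0.29 under nicotinamide and 0.61 in toc1-1 with no change in mean level called (0.02 ± 0.06, SE, n = 24 and 24). The remaining named members, in the same order of conditions, were AT2G15020 (1.61, 0.62 and 1.11), AT5G48490 (1.31, 0.58 and 1.08), AT1G55960 (1.16, 0.39 and 0.83), AT5G15950 (1.13, 0.41 and 0.90) and AT4G37550 (0.95, 0.12 and 0.62).

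The pattern held 65 probe sets, 23 of them with a named gene, with median amplitudes of 0.80 in untreated seedlings, 0.12 under nicotinamide and 0.52 in toc1-1. The amplitude of 18 was also called lower in toc1-1 than in untreated seedlings. Their mean level under nicotinamide was lower in 35 and higher in 26. Peaks from 18 to 6 h were more frequent, with 52 of 65 (80%) against 507 of 976 (51.9%) of the other probe sets that were rhythmic in untreated seedlings and toc1-1 (Fisher's exact test, two-sided, odds ratio 3.70, p = 8.21e-06, across probe sets, which are not independent). Of the flavonoid genes that could have passed, 3 of 4 were in the pattern, but their signals near the lower limit under nicotinamide left little room for an amplitude there. The count was 43 without toc1-1 81 h replicate 1 and 39 without the 49 h arrays, the latter chosen after the data were seen, and it ranged from 8 to 109 when a replicate time course was left out.

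**Figure D4:**
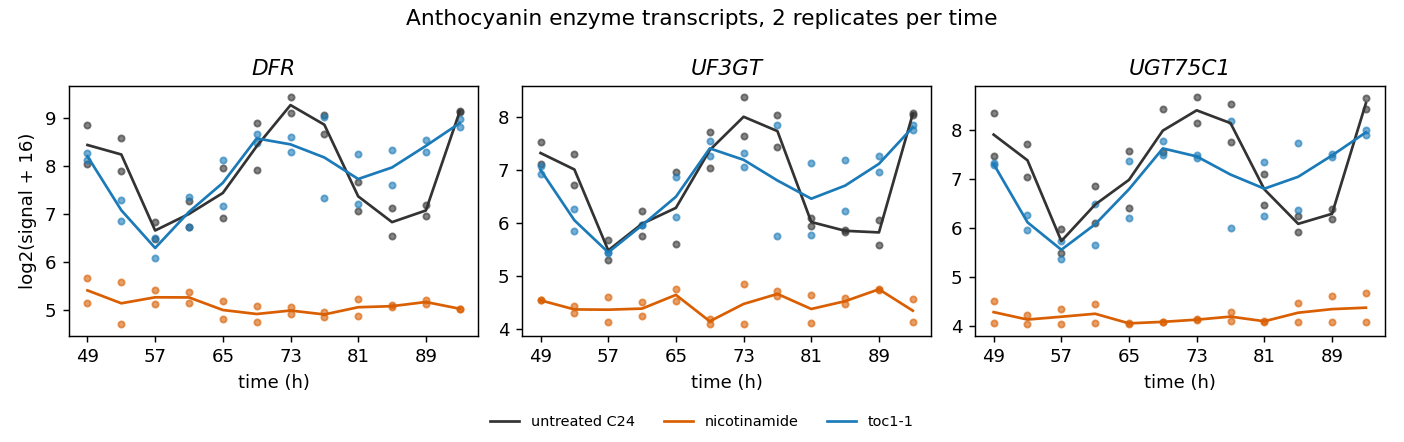
Levels of DFR, UF3GT and UGT75C1 as log2(signal + 16) against time in h. Points are single arrays and lines join the means of the 2 replicates of each condition. The 24 h amplitudes were 1.16, 1.14 and 1.17 in untreated seedlings and 0.05, 0.04 and 0.04 under nicotinamide, where signals lay near the lower limit of the scale.

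The converse pattern, rhythmic in untreated seedlings and under nicotinamide with lower amplitude in toc1-1 than in both, held 15 probe sets. Among the 7 with a named gene were AT3G47160 (0.71 in untreated seedlings, 0.61 under nicotinamide and 0.32 in toc1-1), BGLU44 (0.57, 0.54 and 0.18), AT2G43530 (0.53, 0.64 and 0.09), AT2G43590 (0.49, 0.57 and 0.03), AT2G37480 (0.40, 0.44 and 0.08), AT3G19200 (0.33, 0.31 and 0.05) and AT5G27290 (0.32, 0.33 and 0.05).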

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

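Tests set up only after the result was seen were the split of the untreated arrays and the level under nicotinamide, as were the bounds for the repeat with own periods, itself fixed earlier. Ubiquitin control probe sets, which no comparison used, were higher under nicotinamide than in untreated seedlings by 0.39 (3-prime), 0.58 (5-prime) and 0.50 (middle) on the log2 scale, and by 0.38, 0.53 and 0.44 after quantile normalization. The difference of nicotinamide from untreated changed between the first and the second 24 h in 140 probe sets (interaction test in limma), 73 upward and 67 downward, and in 17 without the nicotinamide arrays of 77 h replicate 1 and 85 h replicate 2. Of these, XTH33 went from 0.49 to 1.18 (adjusted p = 0.00374), AT2G14880 from -0.48 to 0.14 (adjusted p = 0.0194), AT1G33811 from -0.46 to -0.96 (adjusted p = 0.0194) and AT5G63180 from -2.57 to -3.14 (adjusted p = 0.0196).

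Chance regrouping of the arrays within times was tested with 100 splits, the real one included. It breaks up the time courses, so none of these counts speaks of differences between whole courses. It also keeps the differences in mean level, called in 10825 probe sets under nicotinamide and 5691 in toc1-1, which widen the spread within mixed groups. The counts for rhythm and amplitude therefore cannot decide chance apart from level. For nicotinamide 2 splits gave as many differences of rhythm as the real 3536 and the highest other gave 7436. A split that exchanges the conditions at some times only makes a mean-level difference vary over the times. Such a difference can be called one of rhythm, though whether this gave the 7436 was not tested. The real split alone reached the count for lower amplitude (1 split; real 496, highest other 50) and higher amplitude (1; 163 and 44). Chance within times was excluded for single times (1; 62622 and 10520). Chance was not excluded for the number of lists called, as 15 splits reached the real count of 1 and the highest other gave 5. For toc1-1 chance within times was excluded for single times (1; 2019 and 215). The real split alone reached the count for the difference of rhythm (1; 982 and 123) and lower amplitude (1; 209 and 5), with the same limit. The real count of 0 for higher amplitude (100; highest other 78) and lists (100; highest other 8) is reached by any split, so nothing was tested there. For mean level 1 split, the real one, gave as many in each comparison (10825 and 4979; 5691 and 5).

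Regrouping of all 3 conditions gave as large a calcium pattern only in the real split (1 of 100; real 65, highest other 2). The mean-level differences were kept there too, so chance is not decided for amplitude apart from level. Reordering the times gave as many rhythmic probe sets in 1 of 100 orders for untreated seedlings (3129, highest other 1822), 1 for toc1-1 (1166 and 564) and 15 for nicotinamide (4371 and 6650), so that chance order is not excluded for nicotinamide. Whole time courses allow 3 splits, too few for a share under 0.05: the real mean-level counts were 10825 and 5691, and the highest others 1781 and 8 (1 of 3 each).

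Genes of root hairs were lower in both comparisons: AT1G30870 (-2.11 under nicotinamide and -1.81 in toc1-1), AT3G49960 (-1.80 and -1.59), EXPA18 (-1.26 and -1.12), EXPA7 (-0.69 and -0.68) and XTH26 (-0.55 and -0.50), all 5 below the expression filter. Their list was written after the fall of root-type peroxidases was seen, so it adds no independent support. All 5 stayed lower in both when each comparison used its own untreated time course, but those differed too little to change a sign, so a cause in the shared untreated samples is not decided. The labels give aerial tissue, yet more root tissue in the untreated samples could account for it and cannot be told apart from a change in expression: replicate differences of these genes had a mean pairwise r of 0.461, above 99.99% of 10000 random sets of like level but under the 0.5 set beforehand. The root-expressed PYK10 stood at 0.00 ± 0.07 in toc1-1 at a mean signal of 3530. Whether that signal came from root was not measured, so this single gene does not decide the share of root. Under nicotinamide PYK10 was lower, at -0.70 ± 0.07. An effect of nicotinamide or of the mutation on expression stays open as untested.

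Chloroplast-encoded transcripts were higher in toc1-1 (median 0.25 over 67 genes). RNA degradation is a candidate explanation, though of the 5-prime controls only actin was lower: with the 3-prime to 5-prime ratio of control transcripts as covariate the median was -0.07, or -27.2% of its size, and 14 genes were higher and 8 lower, in place of 27 and 5. Across 36 replicate pairs that ratio followed the chloroplast mean (r = 0.534, permutation p = 0.00102; rho = 0.546, permutation p = 0.00071; r = 0.623 without the 2 farthest pairs). More RNA without a poly(A) tail cannot be told apart, since the 25S covariate left 61.0% of the median, at 0.15, though the 25S level followed the chloroplast mean (r = 0.69, rho = 0.725, permutation p = 1e-05 for each, the smallest they can give; r = 0.654 without the 2 farthest; adjusted over the 2 relations, p = 2e-05 here and unchanged for the ratio). An effect of the mutation on chloroplast transcripts was not tested apart from these.

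The lower 24 h amplitude under nicotinamide than in both untreated seedlings and toc1-1 (65 probe sets) might reflect a period other than 24 h. With the period of each condition, 25.7 h under nicotinamide from 3 genes, 84.6% (55 of 65) were called again. So small a change of period could hardly alter the call, and the median amplitude under nicotinamide went from 0.12 to 0.14. Longer periods or periods of single genes were not tested, so they are not decided. A low 24 h amplitude does not mean that no rhythm was left. AT2G15020 still ranged from 6.25 to 8.45 on the log2 scale in nicotinamide replicate 1, and from 6.28 to 8.73 in replicate 2. Levels near the lower limit under nicotinamide cannot be told apart for part of them, as 26.2% (17 of 65) lay under 32 signal units, DFR, UGT75C1 and UF3GT among them. A link to the calcium oscillation stays open, since no calcium was measured on these arrays.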

How the results depend on the processing

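The alternatives without 49 h, without the outlying arrays and with all probe sets rhythmic in all conditions were chosen after the result was seen. Of 3011 recomputed values for 141 named results, 2790 kept their direction and side of the threshold, 206 lost the call, 14 gained one and 1 reversed, GLR3.3 under nicotinamide, which ranged from -0.47 to 0.057 when a nicotinamide replicate was left out. The counts below moved by over 1.5 times, or the periods by over 1 SD. The closing ranges with a replicate time course left out are given whether or not they moved so far. The cause was not tested except where fewer samples, fewer probe sets or a stricter limit give it. For toc1-1 counts without nicotinamide arrays the cause was the spread shared by all conditions.

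Quantile normalization gave 3130 single-time calls in toc1-1 and 4 nicotinamide lists. A pseudocount of 1 gave a toc1-1 period of 21.55 h; one of 64 gave 248 higher amplitudes under nicotinamide and 317 lower in toc1-1. No filter gave 2 higher amplitudes in toc1-1, and the upper 40% gave 4019 lower levels under nicotinamide. At an adjusted p under 0.01, 2251 were rhythmic under nicotinamide and 688 in toc1-1, rhythm differed in 2250 and 571, amplitude was lower in 315 and 92 and higher under nicotinamide in 49, 1997 were higher in toc1-1, 698 single-time calls remained there by number, and the calcium pattern held 27. At 1.5-fold, 1853, 1958 and 699 were rhythmic in untreated seedlings, nicotinamide and toc1-1, rhythm differed under nicotinamide in 2137, and mean levels were higher and lower in 1547 and 2887 under nicotinamide and 187 and 220 in toc1-1.

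The replicate block, tried because the conditions share 2 replicate numbers that the labels tie to no common batch (correlations across probe sets of replicate differences between conditions were 0.522, 0.225 and 0.183), gave 253 higher amplitudes under nicotinamide. The random block (correlation 0.16) gave 326, with 367 lower in toc1-1, 835 higher and 991 lower levels in toc1-1 and a calcium pattern of 102. Without arrays of title ending in 2, which takes away both 65 h arrays of nicotinamide, 2367 were rhythmic under nicotinamide. Own periods gave 130 lower amplitudes in toc1-1. Cosine residuals gave 106 higher amplitudes under nicotinamide, 52 lower in toc1-1 and a pattern of 27. Series means gave 103 and 198 in toc1-1. A removed trend gave 21.55 h, and GI alone gave 24.35, 26.8 and 21.1 h. Camera with an estimated correlation called 0 lists under nicotinamide, and fry 8, with 3 in toc1-1. Without the outlying arrays 3321 single-time calls were made in toc1-1, and without 49 h, 99 amplitudes were higher under nicotinamide and the pattern held 39. All probe sets rhythmic in all conditions gave 26.65 and 22.05 h.

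With a replicate time course left out, where the lone arrays were taken to vary like the others, counts ranged for rhythmic from 1305 to 4608 (untreated), 2859 to 5306 (nicotinamide) and 211 to 2091 (toc1-1). For nicotinamide, rhythm differed in 1646 to 5095, amplitude was lower in 243 to 519 and higher in 16 to 1308, levels were higher in 3818 to 4527 and lower in 5822 to 7090, and single times gave 39027 to 74415. For toc1-1, rhythm differed in 268 to 1842, amplitude was lower in 3 to 508, levels were higher in 1549 to 4048 and lower in 1765 to 3240, and single times gave 258 to 9106. The pattern held 8 to 109. Periods were 23.4 to 24 h, 25.2 to 26.2 h and 21.6 to 21.7 h. Low signals limit small folds through the added 16 units.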

Other observations

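The test of overlap was chosen only after the result was seen, and the families were defined after the array annotation was read but before levels were looked at. Autophagy genes rose under nicotinamide: 7 of 8 members, such as ATG8B (1.64 ± 0.08, SE, n = 24 and 24), ATG8E (1.54 ± 0.07) and ATG8D (0.65 ± 0.07), while ATG8F fell (-0.38 ± 0.07; camera adjusted p = 0.0391, adjusted p = 0.152 with an estimated correlation). Of 9 beta-glucosidases 8 fell, BGLU28 at -2.61 ± 0.23, BGLU44 at -2.39 ± 0.08 and BGLU15 at -1.90 ± 0.08 (camera adjusted p = 0.0391, adjusted p = 0.447 with an estimated correlation). Of 14 trichome birefringence-like genes, a family of cell-wall acetyltransferases, 10 fell and 1 rose, with TBL36 at -2.21 ± 0.06 and TBL37 at 1.43 ± 0.05 (camera adjusted p = 0.0484, adjusted p = 0.152 with an estimated correlation). After quantile normalization the counts were 7 higher and 1 lower for autophagy, 1 higher and 8 lower for beta-glucosidases, and 3 higher and 9 lower for the trichome birefringence-like genes.

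Further families under nicotinamide, not called by camera, were UDP-glycosyltransferases (16 higher and 11 lower of 29), serine carboxypeptidase-like genes (0 and 3 of 4), cytochromes P450 (5 and 3 of 13), tau glutathione S-transferases (2 and 3 of 8), expansins (2 and 5 of 9), xyloglucan endotransglucosylases (2 and 2 of 5, median -0.14 and mean 0.17), SWEET sugar transporters (4 and 4 of 8, with SWEET2 at 1.88 ± 0.09 and SWEET17 at -2.11 ± 0.10), ubiquitin-conjugating and ubiquitin-specific protease genes (9 and 7 of 22), chloroplast-encoded genes (18 and 37 of 67), calmodulin-like genes (1 and 1 of 4) and IQ-domain genes (1 and 4 of 6). The Aux/IAA gene measured was higher (1 of 1). The mean of the chloroplast-encoded genes was 9.89 in nicotinamide replicate 1 and 9.28 in replicate 2, against 9.94 and 9.89 in untreated seedlings and 10.12 and 10.32 in toc1-1.

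In toc1-1 the same families gave UDP-glycosyltransferases 7 higher and 3 lower, serine carboxypeptidase-like genes 0 and 2, cytochromes P450 4 and 1, beta-glucosidases 1 and 2, tau glutathione S-transferases 0 and 2 (median 0.05 and mean -0.12), xyloglucan endotransglucosylases 1 and 2, trichome birefringence-like genes 1 and 4, SWEET sugar transporters 1 and 4, ubiquitin-conjugating and ubiquitin-specific protease genes 4 and 2, calmodulin-like genes 1 and 2, autophagy genes 0 and 2, IQ-domain genes 1 and 1 and Aux/IAA 0 and 0. None of these was called by camera.

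Fold changes of nicotinamide and toc1-1 against the same untreated arrays had a correlation of 0.268 across probe sets, and 0.12 and 0.352 with separate untreated time courses, against 0.499 in simulated data with no effect. The simulated correlation follows from the shared control and the equal spread set there, so it is no test of the observed one. The covariance of the fold changes was 0.0471, against 0.00278 in the simulated data. Simulated arrays were independent, whereas arrays of the same time course had a correlation of 0.16, so the covariance is no test either. Lower in both were 1584 probe sets, with 1294 expected for independent calls, and higher in both 1277, with 934 expected; sharing of the untreated arrays adds to both.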
